A study of Mus musculus with 13 samples.

How the data were processed

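Fetal livers of mice at 14.5 days post coitum gave 13 libraries, of which 9 were mRNA and 4 were chromatin libraries. The mRNA came from 3 Klf1 genotypes with 3 replicates each. Per the labels, globin transcripts were depleted with a hybridisation kit and poly(A) RNA was then sequenced on an Ion Proton instrument. Chromatin immunoprecipitated with a KLF1 antibody, and its input, came from wildtype and MommeD45 livers. Per the labels, each chromatin library was made from 2 pooled replicates.

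The deposited gene table holds the authors' cuffdiff comparisons of the 3 genotypes, whose codes are given in the design text of the series. TopHat2 2.0.10 and genome build mm9 come from the submitters' processing notes, while the cuffdiff version, annotation and options are not given in the sources used here. The table lists 3099 results for 2036 genes, and each is marked significant. Per the file headers it gives 1 abundance per genotype, a log2 ratio, a p-value and a q-value. The abundance is taken to be FPKM from the column layout of cuffdiff, because the deposited table does not name its unit. Values of single replicates were not analysed here, so no SD, n or other grouping of libraries stands beside a value, and the sequencing depth is unknown. A gene missing from a comparison in the authors' table had not passed their threshold or was not tested. The deposited log2 values have no pseudocount and were turned so that each is the first-named genotype over the second.

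The deposited q-values were traced to 1 Benjamini-Hochberg adjustment over the 3 comparisons together. Multiplying q by the rank of p and dividing by p gave between 38893.9 and 38894.1 tests at all 80 distinct p-values. The mean of 12965 tests per comparison was used as the number of genes tested, which is an assumption. The smallest listed p was 5e-05 and the smallest listed q was 0.00159.

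Peaks were called by the authors with MACS2, after paired-end mapping to mm9 with Bowtie2 and removal of duplicates with Picard, per the deposited description sheet. Per the file headers, each peak has a pileup signal, a fold enrichment over the local background, and −log10 of its p-value and q-value. These are the authors' values and served only to describe, rank or filter peaks within a list. Peaks split into several summits were counted once, at the summit of highest fold enrichment. With 1 library per genotype, no test between genotypes was possible for the peaks.

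Calls were counted at the authors' q of 0.05. Overlaps of calls were set beside the number for independent lists and beside 100 simulations of unchanged groups that shared libraries, cut to the observed list lengths. For 18 gene lists fixed before the data were examined, the lower and higher called members were compared with all other called genes by two-sided Fisher's exact test. Those p-values were adjusted by Benjamini-Hochberg within each comparison. Only called genes have p-values in the deposited table, so no adjustment over a list's genes was made. Peaks sharing at least 1 base were counted as shared (bedtools 2.31.1), and a peak within 10 kb of a gene's locus in the authors' table was counted as near it. Strengths of shared and unshared peaks were compared by a two-sided permutation test with 100000 resamples. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Genes and peaks are not independent replicates. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

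The direction test was tested on simulated lists. With 12 called members each, of which 11 were higher, 100% of planted lists passed in every comparison. Every planted list had these same counts, so its unadjusted p was the same in each draw and the 100% is no recovery rate. Lists with fewer called members, as all were in D45/- against +/-, are not covered. Random lists passed in 0.444% of cases for D45/- against +/- (228 genes), 2.67% for -/- against +/- (1786 genes) and 2.00% for D45/- against -/- (1085 genes).

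Genes were named by a rule fixed beforehand: Klf1, the 5 highest and 5 lowest called genes by log2 ratio, up to 3 called members of each list by size of change, and called globin genes. The rule left out genes at 0 in a group and genes under 1 FPKM in the higher group among the extremes. It gave 41, 63 and 61 genes in the 3 comparisons, and the text names part of them; some genes that the rule takes are not reported here. For peaks it took the 5 strongest of each list and those within 10 kb of a named gene, except that the merged row Hbb-b1,Hbb-b2 was not searched. Symbols are those of the authors' table. Rows of gene families such as the globins and stefins may share reads between near-identical copies.

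Alternatives covered stricter q, abundance filters of 1 and 5 FPKM, a minimum log2 change, a pseudocount of 1, other definitions of a shared peak and other distances to genes. The search for KLF1 sites in peaks was not run, because no mm9 sequence was used here.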

Results

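Gene expression and KLF1 binding were measured in mouse fetal liver at 14.5 days post coitum, when the liver is mainly a site of red cell production. KLF1 is a zinc finger transcription factor of red cell precursors. mRNA was sequenced from livers with 1 intact Klf1 allele (+/-), with the MommeD45 allele over a null allele (D45/-) and with no intact allele (-/-), in 3 replicates each. The series title places the mutation in a linker between zinc fingers of KLF1 and asks about membrane transporters, cytoskeletal proteins and hemolysis. KLF1 binding was measured by ChIP-seq in wildtype and MommeD45 livers, with 1 library per genotype made from 2 pooled replicates. Whether the MommeD45 ChIP livers carried 1 or 2 copies of the allele is not given in the sources used here. The authors' deposited table gives 1 abundance (FPKM) per genotype for genes that passed their test, so the spread between replicates is unknown. Globin values were measured after depletion of globin transcripts.

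Klf1 itself was measured at 378 FPKM in +/-, 398 in D45/- and 34.8 in -/- livers in the authors' deposited table. Klf1 was called lower in -/- than in +/- (log2 ratio -3.44, q 0.00159) and was not called between D45/- and +/-.

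The comparison of -/- with +/- sets livers with no intact Klf1 allele against livers with 1. The authors' deposited table called 1786 genes, 879 lower and 907 higher in -/-, or 13.8% of the tests assumed for this comparison. Among genes of at least 5 FPKM in the higher genotype, 821 were lower and 564 higher. Epb4.9, which encodes the membrane skeleton protein dematin, was at 0.400 FPKM in -/- and 112 in +/- in the authors' deposited table (log2 ratio -8.13). Fn3k, a kinase that repairs glycated proteins, was at 0.376 against 52.4 FPKM there, and Nxpe2 at 0.825 against 79.2. Sowaha (log2 ratio -7.76) and the glucose transporter gene Slc2a4 (-5.63) completed the 5 lowest genes of the authors' deposited table. Among the 5 highest genes of the authors' deposited table were the chemokine gene Ccl2 (24.3 against 0.562 FPKM), Rgs4 (1.90 against 0.0669) and Isoc2b (4.79 against 0.216).

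Called genes of 5 lists, heme synthesis, membrane cytoskeleton, surface proteins, transporters and maturation, were mostly lower in -/- livers. Heme synthesis had 12 of 16 genes called lower and 0 higher (adjusted p = 0.000857, Fisher's exact test). The authors' deposited table gave 72.9 against 814 FPKM for Alad, an enzyme of that pathway, and 52.8 against 554 FPKM for Slc25a37, which carries iron into mitochondria. The membrane cytoskeleton list had 12 of 25 genes lower and 2 higher (adjusted p = 0.0115, Fisher's exact test). Ank1, which encodes ankyrin, was at 47.2 against 309 FPKM in the authors' deposited table. Blood group and surface proteins had 10 of 20 lower and 1 higher (adjusted p = 0.0110, Fisher's exact test), with Icam4 at 25.5 against 259 FPKM in the authors' deposited table. Membrane transporters had 18 of 40 lower and 4 higher (adjusted p = 0.00552, Fisher's exact test). Among them, the authors' deposited table gave log2 ratios of -4.32 for the amino acid transporter gene Slc43a1, -4.07 for Slc22a4 and -3.19 for the potassium channel gene Kcnn4. Maturation, mitophagy and enucleation had 12 of 24 lower and 0 higher (adjusted p = 0.000857, Fisher's exact test).

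Regulators of red cells and of the cell cycle were also lower in -/- livers. Erythroid transcription factors had 12 of 25 genes lower and 1 higher (adjusted p = 0.00459, Fisher's exact test), with log2 ratios of -3.14 for Sox6 and -2.70 for Klf3 in the authors' deposited table. Cell cycle and replication had 16 of 32 lower and 1 higher (adjusted p = 0.000857, Fisher's exact test). The cell cycle transcription factor genes E2f2 and E2f4 had log2 ratios of -3.31 and -2.36 in the authors' deposited table. The cell cycle and transporter lists no longer passed when only changes of at least 1 on the log2 scale with a pseudocount of 1 were kept (adjusted p = 0.0585 for both, Fisher's exact test). Iron handling had 6 of 17 genes lower and 1 higher, which did not pass (adjusted p = 0.0846, Fisher's exact test). Glycolysis and red cell redox was split, with 5 of 26 lower and 5 higher. Named in full, beyond the rule, its lower members were Hk1, Pklr, Prdx2, Gpx1 and Txnrd2. Pklr, the red cell pyruvate kinase gene, was at 34.4 against 354 FPKM in the authors' deposited table. The 5 higher were the glycolysis genes Gpi1, Aldoa, Pgk1, Pgam1 and Pkm, with log2 ratios between 0.999 and 1.58 there.

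Globin genes went both ways in -/- livers. The authors' deposited table gave the merged adult beta-globin genes Hbb-b1,Hbb-b2 61.4 FPKM in -/- and 1123 in +/-. The embryonic alpha-like gene Hba-x was also lower there (log2 ratio -2.19), as was Hbq1a (-2.10). The embryonic beta-like genes Hbb-y and Hbb-bh1 were higher, at 10394 against 2554 and at 883 against 196 FPKM in the authors' deposited table. The list as a whole, with 3 of 12 genes lower and 2 higher, did not pass (adjusted p = 0.768, Fisher's exact test).

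Markers of other blood cells were higher in -/- livers. Of 22 megakaryocyte markers, 19 were called higher and 0 lower (adjusted p = 6.5e-05, Fisher's exact test), with a median log2 ratio of 1.11. Plek had a log2 ratio of 1.41 and Itgb3 of 1.33 in the authors' deposited table. Granulocyte markers had 9 of 18 higher (adjusted p = 0.00869, Fisher's exact test), with the neutrophil elastase gene Elane at 76.5 against 23.7 FPKM in the authors' deposited table. Interferon response genes had 13 of 25 higher (adjusted p = 0.000857, Fisher's exact test), several of them at low abundance, such as Oasl2 at 3.53 against 0.801 FPKM in the authors' deposited table. Macrophage markers had 6 of 22 higher (adjusted p = 0.0467, Fisher's exact test), which did not pass at a q under 0.01 (adjusted p = 0.133, Fisher's exact test). Stress and p53 response genes also had 6 of 22 higher (adjusted p = 0.0467, Fisher's exact test), and Trib3 rose from 3.13 to 33.4 FPKM in the authors' deposited table. Stem and early progenitor markers (5 of 20 higher), endothelial and stromal markers (4 of 20) and hepatocyte markers (1 of 22) did not pass (adjusted p = 0.0846, 0.150 and 1, Fisher's exact tests). None of these lists had a member called lower.

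**Figure D1:**
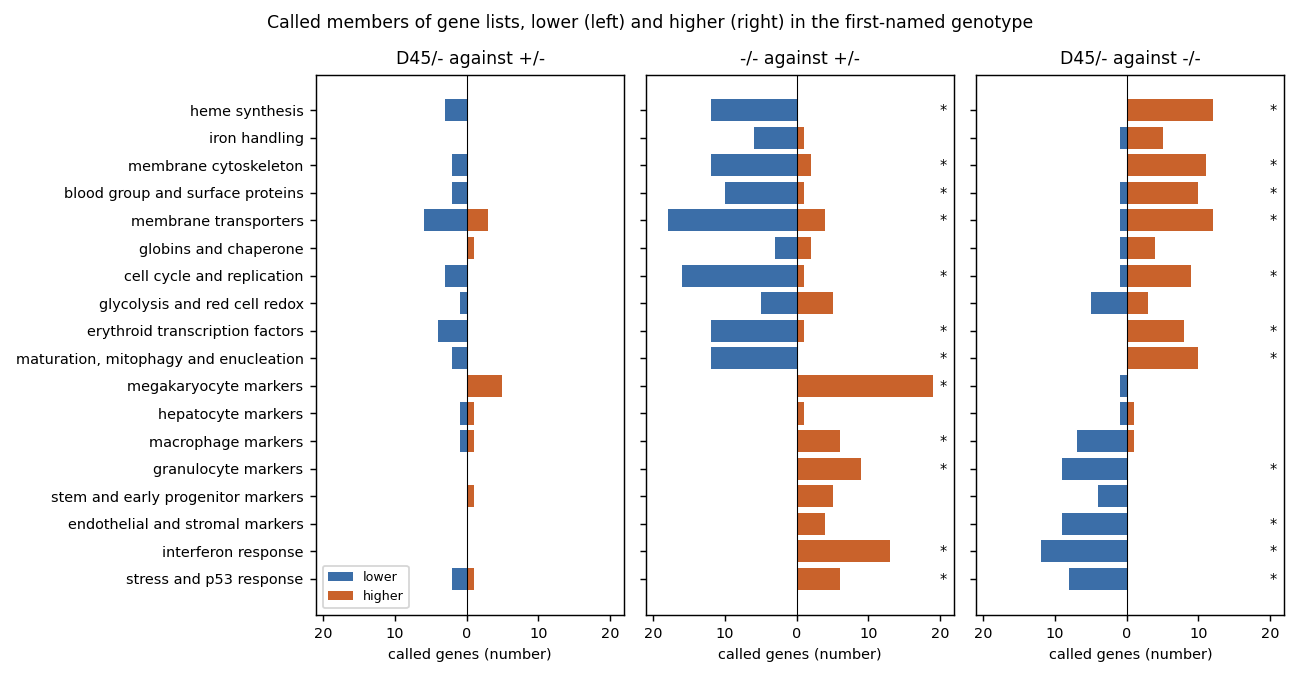
Number of called genes in each of 18 gene lists, lower (left bars) and higher (right bars) in the first-named genotype, for the 3 comparisons of the authors' deposited table. Asterisks mark lists with an adjusted p under 0.05 by Fisher's exact test: 0 lists for D45/- against +/-, 12 for -/- against +/- and 11 for D45/- against -/-.

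The comparison of D45/- with +/- sets the MommeD45 allele against an intact one, each over a null allele. The authors' deposited table called 228 genes, 142 lower and 86 higher in D45/-. The 5 lowest were Nxpe2 (5.19 against 79.2 FPKM), Slc2a4 (0.714 against 10.7), the phosphatase gene Phospho1 (1.08 against 15.8), Paqr6 (0.820 against 8.20) and Fn3k (5.27 against 52.4) in the authors' deposited table. Of the transporter list, which is the longest, 6 of 40 genes were lower and 3 higher. The authors' deposited table gave 31.0 against 172 FPKM for Slc43a1 and 159 against 690 FPKM for the glucose transporter gene Slc2a1. Of the cytoskeleton list, Epb4.9 (24.3 against 112 FPKM) and Tmcc2 (326 against 701) were lower in the authors' deposited table, as were the surface protein genes Darc (4.42 against 19.7), which encodes the Duffy antigen receptor, and Icam4 (119 against 259).

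Single genes of the cell cycle, red cell metabolism and transcription lists were also lower in D45/-. The authors' deposited table gave log2 ratios of -1.28 for E2f2, -1.06 for E2f4, -1.08 for Pklr and -1.04 for Klf3. Heme synthesis had 3 of 16 genes lower, Tspo2 (-0.90), Slc25a37 (-0.87) and Slc25a39 (-0.73), in the authors' deposited table. Maturation had 2 of 24 genes lower, cell cycle and replication 3 of 32, erythroid transcription factors 4 of 25 and glycolysis and red cell redox 1 of 26, with 0 higher in each. Iron handling, granulocyte, endothelial and stromal, and interferon lists had 0 called genes in this comparison of the authors' deposited table.

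Genes higher in D45/- included the carbonic anhydrase gene Car1 (299 against 62.4 FPKM), the butyrophilin gene Btn1a1 (36.7 against 8.08) and the cardiac actin gene Actc1 (3.87 against 0.594) in the authors' deposited table. The embryonic globin gene Hbb-bh1 was at 555 against 196 FPKM there and was the only called gene of the globin list. Megakaryocyte markers had 5 of 22 genes higher and 0 lower, with a median log2 ratio of 0.83 (p = 0.00709, adjusted p = 0.0992, Fisher's exact test). None of these 5 calls passed with q recomputed within the comparison (0.0528 to 0.136) or at a q under 0.01. The heat shock genes Hspa1b and Hspa1a were lower (log2 ratios -2.27 and -1.55), and Trib3 was higher (1.10), in the authors' deposited table. Macrophage markers split, with Clec4f higher (1.70) and Marco lower (-1.53), as did hepatocyte markers, with Cps1 higher (1.02) and Serpina1b lower (-0.95), in the authors' deposited table. The progenitor marker Slamf1 was higher (1.03) there. No list passed the direction test in this comparison; the smallest adjusted p was the 0.0992 of the megakaryocyte list (Fisher's exact test). Most lists had too few called genes to pass: 3 genes, all lower, gave an unadjusted p of 0.292 by Fisher's exact test.

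With q recomputed within this comparison alone, 131 of the 228 calls passed, 88 lower and 43 higher. Of the 41 named genes, 11 then did not pass: Tspo2, Slc25a37, Slc25a39, Cdkn2d, Bcl11a, Rnf123, Rab27b, Mmrn1, Plek, Slamf1 and Trib3.

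**Figure D2:**
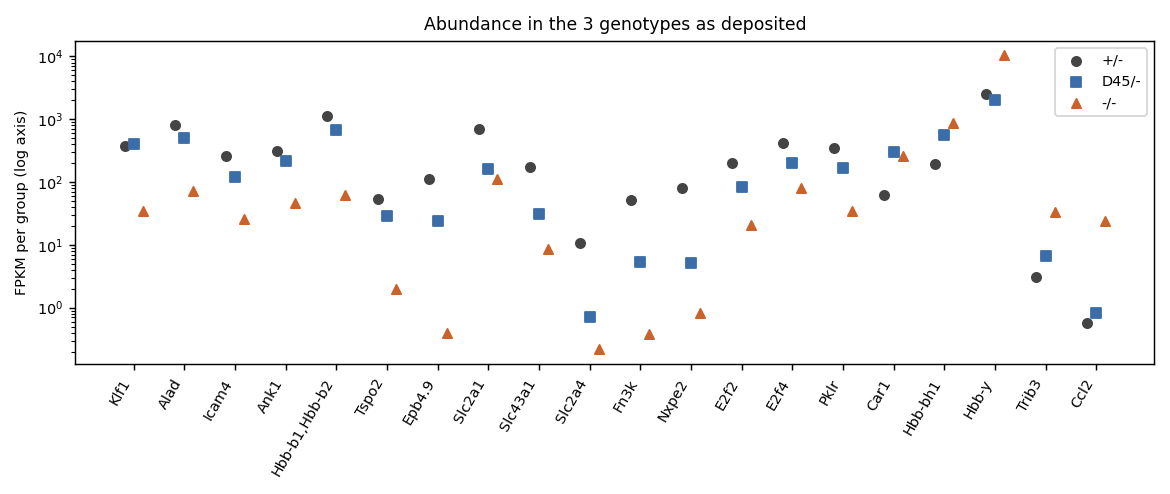
Abundance (FPKM, log axis) of 20 genes in +/- (circles), D45/- (squares) and -/- (triangles) livers, 1 value per genotype from the authors' deposited table. Slc2a1 lay at 159 FPKM in D45/- and 111 in -/-, while Klf1 lay at 398 in D45/- and 34.8 in -/-.

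The comparison of D45/- with -/- sets livers with the MommeD45 allele over a null allele against livers with no intact allele. The authors' deposited table called 1085 genes, 451 higher and 634 lower in D45/-; among genes of at least 5 FPKM in the higher genotype these were 417 and 397. The 5 highest were Epb4.9 (log2 ratio 5.92), Sowaha (5.40), Tspo2 (3.88), Fn3k (3.81) and the beta-globin row Beta-s (3.79) in the authors' deposited table. Heme synthesis had 12 of 16 genes higher and 0 lower (adjusted p = 0.000439, Fisher's exact test), with Alad at 504 against 72.9 FPKM in the authors' deposited table. The cytoskeleton list had 11 of 25 higher and 0 lower (adjusted p = 0.000536, Fisher's exact test), with Add2, an adducin gene, at 285 against 50.9 FPKM and Ank1 at 219 against 47.2 in the authors' deposited table. Transporters had 12 of 40 higher and 1 lower (adjusted p = 0.000888), maturation 10 of 24 higher and 0 lower (0.000871), and surface proteins 10 of 20 higher and 1 lower (0.00300), all by Fisher's exact test. Erythroid transcription factors had 8 of 25 higher and 0 lower (adjusted p = 0.00300) and cell cycle genes 9 of 32 higher and 1 lower (0.00501), by Fisher's exact test. Of the globin list, 4 of 12 genes were higher, including Hbb-b1,Hbb-b2 (log2 ratio 3.47) and Hba-a2 (1.66), and Hbb-y was lower (-2.38), in the authors' deposited table (list adjusted p = 0.200, Fisher's exact test). Iron handling had 5 of 17 higher and 1 lower (adjusted p = 0.131), and glycolysis and red cell redox 3 of 26 higher and 5 lower (1), by Fisher's exact test.

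Several lists had called genes mostly or wholly lower in D45/- than in -/-. Among the 5 lowest genes were Sele, which encodes an adhesion molecule of endothelium, the hepcidin gene Hamp, and the chemokine genes Ccl2 and Cxcl1, at log2 ratios between -5.69 and -4.84 in the authors' deposited table. Interferon response genes had 12 of 25 lower (adjusted p = 0.00501), granulocyte markers 9 of 18 (0.0228), endothelial and stromal markers 9 of 20 (0.0228) and stress genes 8 of 22 (0.0393), with 0 higher in each, by Fisher's exact test. Ddit4 was at 1.65 against 21.6 FPKM and Elane at 30.1 against 76.5 in the authors' deposited table. Of the megakaryocyte markers, Clec1b alone was called lower (log2 ratio -0.79 in the authors' deposited table) and 21 of 22 were not called. Macrophage markers (7 of 22 lower, 1 higher), stem and early progenitor markers (4 of 20 lower) and hepatocyte markers (1 lower, 1 higher) did not pass (adjusted p = 0.192, 0.192 and 1, Fisher's exact tests). With a minimum log2 change of 1 at a pseudocount of 1, the cell cycle, granulocyte, endothelial, interferon and stress lists no longer passed (adjusted p = 0.248, 0.0849, 1, 0.0849 and 0.0849, Fisher's exact tests). At a q under 0.01 the cell cycle, granulocyte and endothelial lists did not pass (0.126, 0.0682 and 0.115) and iron handling did (0.0301), by Fisher's exact test.

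Across the comparisons, genes lower in -/- were grouped by whether they were called in the comparisons with D45/-. Of the 879, 117 were also called lower in D45/- than in +/-, and 50 of these lay above -/- at the same time, among them Epb4.9, Slc43a1, E2f2 and E2f4. Another 334 were called above -/- in D45/- with no call against +/-, among them Alad and Ank1, and 427 had neither call. Absence of a call does not show a return to the +/- level. Alad was at 504 FPKM in D45/- against 814 in +/-, and Ank1 at 219 against 309, in the authors' deposited table. Of the 907 genes higher in -/-, 48 were also higher in D45/-, 481 were lower in D45/- than in -/- with no other call, and 376 had neither. The 117 genes had a median log2 ratio of -2.17 in -/- and -1.12 in D45/-, by the authors' deposited table.

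Of the 228 genes called in D45/-, 168 were also called in -/- against the same +/- livers, and 165 of them (98.2%) changed in the same direction. Unchanged groups sharing the +/- libraries gave 99.9% in the same direction. These simulated groups held no true change, unlike -/- livers with 1786 calls. The simulations therefore cannot decide what the agreement in sign means, and no shared effect is read from it. Independent lists of these lengths would share 31.4 genes among 12965 (p = 4.5e-96, Fisher's exact test); per direction, 117 were lower in both against 9.63 and 48 higher in both against 6.02. Unchanged groups sharing the +/- libraries gave 101 shared genes on average and at most 118 in 100 simulations at these list lengths, so part of the excess may come from the shared controls. Of the 131 genes that passed in D45/- with q recomputed, 107 were among the 1786 listed for -/-. D45/- against -/- and -/- against +/- shared 877 genes, all with opposite sign. The common -/- libraries alone give opposite signs, with 0.571% in the same direction in the simulations. Independent lists would share 149 and simulated lists with the common -/- libraries 349, and here too the common libraries may add to the excess.

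KLF1 peaks were compared between wildtype and MommeD45 livers. How many copies of the MommeD45 allele the latter carried is not given, so their peaks cannot be assigned to the altered protein alone. The authors called 1203 peaks in wildtype and 485 in MommeD45. Of the wildtype peaks, 361 (30.01%, exact 95% interval 27.4 to 32.7) overlapped a MommeD45 peak, and of the MommeD45 peaks 362 (74.6%, 70.5 to 78.5) overlapped a wildtype peak. Shared peaks were stronger than others in both lists. Their median fold enrichment was 6.29 against 4.59 in wildtype (permutation p = 1e-05, the smallest possible) and 4.97 against 4.24 in MommeD45 (permutation p = 4e-05). A MommeD45 peak was found for 12 of the 121 wildtype peaks with the lowest fold enrichment (9.92%, exact 95% interval 5.23 to 16.7) and for 95 of the 121 with the highest (78.5%, 70.1 to 85.5). When the wildtype list was limited to its 485 strongest peaks, 50.7% of them were shared.

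**Figure D3:**
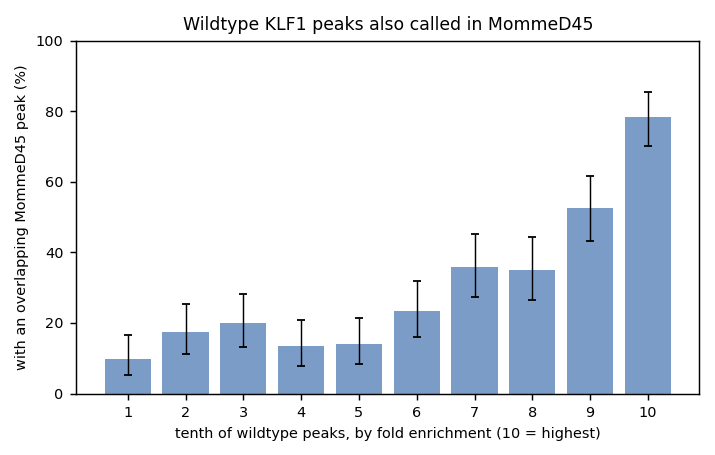
Percentage of wildtype KLF1 peaks with an overlapping MommeD45 peak, in 10 groups from the lowest (1) to the highest (10) wildtype fold enrichment; bars are shares of 120 or 121 peaks and error bars are exact 95% binomial intervals. The share was 9.92% in the lowest group and 78.5% in the highest.

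The strongest wildtype peak lay on chromosome 15 (56455073 to 56455512, mm9) with a fold enrichment of 48.9, and the strongest MommeD45 peak on chromosome 17 (25715873 to 25716352) with 44.9. All 5 strongest peaks of each list were shared, and among them peaks lay within 10 kb of the called genes Dedd2, Pgam1 and Phyhip. Near named genes, shared peaks lay 3.1 kb from Klf1 itself on chromosome 8 (wildtype 87432293 to 87432688, fold enrichment 28.7), inside E2f2 (12.3) and E2f4 (7.21), and at Alad, Ank1, Add2, Ermap, Kcnn4, Gpx1 and Hba-a2. Peaks called in wildtype and not in MommeD45 lay inside Epb4.9 (chromosome 14, 71026840 to 71027080, fold enrichment 4.896), Slc2a4 (5.23), Slc43a1 (3.98), Icam4 (7.84), Prdx2 (6.72) and Rhd (6.53), and 1201 bases from Fn3k (5.90). The one with the highest fold enrichment near a named gene, with the merged row Hbb-b1,Hbb-b2 left out, lay inside Fam160a1 (9.26), a gene higher in D45/-. That merged row had a wildtype peak and no MommeD45 peak within 10 kb, but the strength of its peak was not read. MommeD45 peaks without a wildtype partner lay 448 bases from Klf3 (fold enrichment 3.58) and inside Tfrc (4.06). No peak of either list lay within 10 kb of Slc2a1, Nxpe2, Pklr or Darc.

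Wildtype peaks lay near genes lower in -/- more often than near genes higher in -/-. A peak within 10 kb was found for 261 of 879 lower genes (29.7%, exact 95% interval 26.7 to 32.8) and for 39 of 907 higher genes (4.30%, 3.08 to 5.83), an odds ratio of 9.40 (adjusted p = 3.7e-50, Fisher's exact test). For D45/- against +/- the shares were 31.0% of 142 lower and 10.5% of 86 higher genes (odds ratio 3.84, adjusted p = 0.00033, Fisher's exact test). For D45/- against -/-, 38.4% of the 451 genes higher in D45/- and 3.94% of the 634 lower genes had a wildtype peak (adjusted p = 2.9e-49, Fisher's exact test). MommeD45 peaks were found near 19.5% and 1.89% of the same genes (adjusted p = 1.7e-23, Fisher's exact test), and near 10.6% of genes lower and 1.16% of genes higher in D45/- than in +/- (adjusted p = 0.0063, Fisher's exact test). The comparisons share genes and libraries: of the 1085 genes called between D45/- and -/-, 877 were also called between -/- and +/-, all with opposite sign. These tests are therefore no independent support for one another.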

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

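Of the tests in this part, those on peaks, on the spread of red cell genes and on globins were chosen after the results were seen. 3 genes were called in opposite directions in D45/- and -/- against the same +/- livers, and each was also called between D45/- and -/- by the authors' test. Marco, a macrophage receptor gene, had log2 ratios of -1.53 in D45/- and 0.78 in -/- in the authors' deposited table. Prokr1 had 0.84 and -1.31 there. Stfa1, of the stefin family of near-identical genes, was listed at 0 in D45/-, with 209 FPKM in -/- and 101 in +/- (log2 ratio 1.04 for -/- over +/-) in the authors' deposited table.

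The MommeD45 list held fewer peaks than the wildtype list. Wildtype peaks without a MommeD45 peak had a median fold enrichment that differed by -1.69 from that of shared ones, as needed if weak peaks fell under the calling threshold. The medians behind this difference were already known from the Results, so it is no separate support for that cause. Of the 121 wildtype peaks with the highest fold enrichment, 26 (21.5%, exact 95% interval 14.5 to 29.9) had no MommeD45 peak, above the bound of 5% first set for a weaker library as the whole cause. That bound was not derived from a measured value, and with 1 library per genotype a lower yield and weaker binding of the altered protein cannot be told apart. The number of copies of the allele in these livers is not given, so intact KLF1 may also have been bound at MommeD45 peaks.

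Red cell genes were lower in -/- livers. If a smaller share of red cell precursors were the whole cause, these genes should fall by like amounts; 8 of 45 called lower members of the heme, cytoskeleton, surface and maturation lists (17.8%, exact 95% interval 8.002 to 32.1) lay over 1 log2 unit from their median of -1.56. The test decides nothing, because members that were not called have no value in the authors' table and the 3 called higher were left out. The share of such cells therefore cannot be told apart from a change within them. A block of maturation with retained early erythroid genes was set beside globin calls already known, of which 2, both embryonic, were higher and 3, with the embryonic gene Hba-x, were lower. These calls decide nothing for or against such a block.

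Of the 60 genes called in D45/- and not in -/- against +/-, 3 (5%, exact 95% interval 1.04 to 13.9) lay on chromosome 8, which carries Klf1, against 5.11% of 1976 other called genes (p = 1, Fisher's exact test). Linked strain variants around Klf1 that act on their own chromosome could touch at most those 3 of the 60. They are Fcho1, Klkb1 and Slc12a4, named after their values were seen. For these 3, such variants cannot be told apart from an effect of the allele. The other 57 lay on other chromosomes, and unlinked strain differences were not tested. The 168 genes called in both D45/- and -/- against +/- were not examined for linked variants, and among them E2f4 lies on chromosome 8.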

How the results depend on the processing

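The alternatives with q recomputed within a comparison, and those that count summits separately, drop mitochondrial peaks, shorten the wildtype list or change the locus rule, were chosen after seeing the data. At a q under 0.01 the calls were 130 for D45/- against +/-, 1048 for -/- against +/- and 618 for D45/- against -/-, and 98 genes were shared. At a q under 0.001 all 4 counts were 0, because the smallest q that the authors' table lists is 0.00159. With a log2 change of at least 1 they were 138, 1131 and 686, with 97 shared. With a pseudocount of 1 and a log2 ratio of at least 1 the calls were 87, 743 and 439. Lists that passed were then 9 instead of 12 for -/- against +/- and 6 instead of 11 for D45/- against -/-. For -/- against +/- the cell cycle, transporter and macrophage lists dropped out, the last because it had no called gene left. With q recomputed within the comparison, D45/- against +/- kept 131 calls, of which 107 were among the genes listed for -/- against +/-. The stricter thresholds and fold limits leave fewer genes by construction. In the other comparisons recomputing q could remove no listed gene, and genes it would add have no values in the authors' table, so it says nothing of their stability. Filters of 1 and 5 FPKM kept each total count of calls within 1.5 times. At 5 FPKM, however, -/- against +/- had 821 lower and 564 higher genes, and D45/- against -/- had 397 lower and 417 higher, which turns the balance of the latter.

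Shared wildtype peaks numbered 154 at a −log10 q of at least 10 and 183 at or above the median fold enrichment, where fewer peaks enter. The share of wildtype peaks was 27.0% with a reciprocal overlap of 50% and 50.7% with the shortened wildtype list. The share of MommeD45 peaks was 67.0% with reciprocal overlap, 70.1% with summits within 100 bases, 89.1% at a −log10 q of at least 10 and 51.3% against the shortened wildtype list; the cause was not tested. The greater strength of shared peaks and the link of peaks to gene direction kept their direction and side of the threshold under every alternative run.

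No paired analysis was possible because the authors' table gives 1 value per genotype. For the same reason, leaving out each replicate was not run, and the search for KLF1 sites in peaks was not run without an mm9 sequence. Depth is unknown, so absence of a call or a peak does not show absence of a change.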

Other observations

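Of the tests in this part, each was set before its result was seen, except that of low-oxygen genes in D45/- against -/-, which had no prediction. Genes known to be induced by low oxygen were called higher in -/- livers. Of 26 such genes, put in a list after other values of the table were seen but without those already seen, 19 were called higher in -/- than in +/- and 0 lower (p = 3.6e-06, Fisher's exact test). In D45/- against -/-, 23 were called lower and 0 higher (p = 4.3e-06, Fisher's exact test), and in D45/- against +/- none of the 26 was called in the authors' deposited table. The 19 genes were all among these 23. Both comparisons use the same -/- libraries, which alone give opposite signs, so the second result is no independent support for the first. Examples chosen after their values were seen are Egln3, an oxygen sensor (log2 ratio 3.63 in -/- over +/-), Adm (2.99), Bnip3 (2.96) and Vegfa (1.92), from the authors' deposited table. The glycolysis genes Pgk1 and Aldoa were lower in D45/- than in -/- as well, with log2 ratios of -1.61 and -1.48 in the authors' deposited table. Genes already seen were not in the list, so the 0 lower holds for the 26 only. Outside it, genes went both ways in -/- over +/- in the authors' deposited table. Pgk1 (log2 ratio 1.58) and Aldoa (1.49) were higher, while the glucose transporter gene Slc2a1 (-2.63) and the transferrin receptor gene Tfrc (-1.81) were lower.

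These 19 genes are consistent with low oxygen in -/- fetal livers, which is a hypothesis. Oxygen was not measured, and other causes of the same gene program, such as handling of the tissue or a changed mix of cells, were not tested.

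A further hypothesis was that genes lower in D45/- less often had a KLF1 peak nearby in MommeD45. Among genes lower in -/- with a wildtype peak within 10 kb, 14 of 42 (33.3%, exact 95% interval 19.6 to 49.5) that were also lower in D45/- had a MommeD45 peak. Of the genes called above -/- in D45/- with no call against +/-, 62 of 133 (46.6%, 37.9 to 55.5) had one. The difference of -13.3 percentage points did not pass (p = 0.155, Fisher's exact test), so loss of peaks stays open. The strongest nearby wildtype peak had a median fold enrichment of 5.38 at the first group and 5.25 at the second. The difference of 0.13 (permutation p = 0.627) does not decide whether weaker wildtype peaks at genes lower in D45/- add to it. Of the genes of neither kind, 26 of 86 (30.2%) had a MommeD45 peak within 10 kb. These counts take any MommeD45 peak within 10 kb of the gene, whether or not it overlaps the wildtype peak. The MommeD45 ChIP livers are not stated to be D45/-, so their peaks may not be those of the D45/- mRNA livers.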
